A study of Mus musculus with 10 samples.

How the data were processed

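The series holds 10 tongue libraries of C57BL/6J mice exposed to 4NQO, 4 labelled vehicle and 6 whose treatment is given as SP2509. The titles of these 6 read SP2509h, and the labels do not say what the h stands for. Per the labels' protocols, RNA was extracted with TRIzol, cleaned on columns and enriched for poly-A RNA on poly-T beads, and cDNA was primed with random hexamers. The submitters' processing notes name HISAT2, featureCounts and the mouse build mm10, without versions or roles. The annotation release, the strand setting of the counting and the tool behind the scaling are not given in the sources used here.

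The deposited signal values are read counts per gene divided by 1 size factor per library. No label states this, and it was read from the values: in each library every value lay within 0.01 of a whole multiple of the library's smallest value above 0 (100% of values). Size factors recomputed from the recovered whole reads by DESeq2's median of ratios differed from the deposited scaling by at most 6.42e-08 percent. The table lists 27151 genes by Ensembl ID, the smallest row total is 10 reads, and 27113 IDs were matched to a symbol. Coordinates and biotypes come from GENCODE M21 on GRCm38, the same build as mm10. Whole reads summed to 9180844, 12911863, 11690605 and 14768955 in vehicle replicates 1 to 4 and to 17621512, 15748571, 16333204, 15762566, 18127883 and 19375555 in SP2509 replicates 1 to 6. Outside mitochondrial genes the group means were 6721805 and 12476189 reads. One read is worth 0.898 to 1.85 normalised reads in vehicle and 0.727 to 0.873 in SP2509, so low genes are measured more coarsely in vehicle.

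The main test was limma (3.58.1, R 4.3.3) with an intensity trend and robust empirical Bayes on log2(value + 1), two-sided, over all 10 libraries with no covariate, on 17088 genes with a value of at least 10 in at least 4 libraries. Fold changes are on the log2(value + 1) scale, which understates the change of low genes, and the median over all tested genes was 0.02. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The design named 38 gene lists before the data were examined, and 36 of them with at least 4 tested members entered camera with a preset correlation of 0.01, adjusted over the 36 lists. Beside it stand camera with an estimated correlation, fry, which asks whether a list's genes move one way on balance without comparing them with other genes. An exact permutation test was run on the mean log2 value of a list per library (210 regroupings of 10 libraries, 70 of 8 units). Adjusted over the 36 lists, no exact permutation test passed.

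The genes named in the text follow a rule fixed at the same time: 18 genes tied to the series title whatever their values, the 10 higher and 10 lower called genes with the largest log2 fold change, an official symbol and a mean of at least 50 in the higher group, and 2 to 4 members with the smallest p of each list described. Genes outside the rule (Muc5b, Gapdh, Trbc1, Fbln1, Lum, Cfd and those of the closing observations) were chosen after their values were seen. Some genes that the rule takes are not reported here.

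Replicates were compared before they were averaged, by the spread of the 2 values of a pair relative to the Poisson expectation in bins of read count. SP2509 replicates 1 and 2, and 4 and 5, were treated as 1 unit each in means, SDs and n, and the fit of 4 vehicle libraries against 4 SP2509 units is printed beside the 10-library fit. The labels do not say whether each library came from its own mouse, so p-values measure the spread between these libraries, which may be technical in part. Counting error of low genes is given as reads per group. The numbers of vehicle and SP2509 replicates were not used to pair libraries.

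The alternatives were the pseudocount, the filter, 2 rescalings, limma without trend, library weights, a replicate block, each library left out, a muscle covariate, edgeR (4.0.16) and DESeq2 (1.42.0) on the recovered whole reads, other thresholds, the merged pairs, groups of libraries left out, a transcript length and GC correction (values for 99.9% of tested genes), thinning to 4730016 reads outside mitochondrial genes, and a keratinocyte covariate. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

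The scripts were tested on simulated data drawn from the real means and size factors of 27151 genes and the dispersion trend over the mean. In the tests of recovery 200 genes with a mean of at least 50 were changed. The rates below do not cover lower genes or genes whose spread departs from the trend. With 10 independent libraries, 1.5% of genes changed 1.5-fold, 57.2% of genes changed 2-fold and 98.8% of genes changed 4-fold were called in the right direction, with 0%, 5.25% and 4.81% of calls false. A draw without any call drops out of these averages, so the 1.5% may be too high. Recovery was not measured with close pairs of libraries, as the real data hold, and may be lower there. With no effect and 2 of the 4 SP2509 units holding 2 libraries each, 9.01% of genes had an unadjusted p under 0.05 when the 10 libraries were counted separately and 5.01% with the pairs merged. Neither fit called a gene in any of 20 draws. A list raised 1.5-fold was found by camera in 10 of 10 draws, with 2 calls of other lists in all draws together. Genes varied independently in these draws, so they do not show how often camera calls lists whose members vary together. In the real libraries 74 of 100 splits gave 8 or more called lists.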

Results

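Tongue RNA of C57BL/6J mice exposed to 4NQO, a carcinogen that induces oral lesions, was sequenced after treatment with vehicle (4 libraries) or with SP2509 (6 libraries), an inhibitor of the histone demethylase LSD1, which the gene Kdm1a encodes. The table held normalised read counts for 27151 genes. The whole reads behind them summed to between 9180844 and 14768955 per vehicle library and between 15748571 and 19375555 per SP2509 library. Mitochondrial genes took 45.2% ± 7.24 (SD, n = 4) of the reads in vehicle and 28.1% ± 3.37 (SD, n = 4 SP2509 units, defined next) in SP2509. The groups did not overlap (exact permutation test, two-sided, p = 0.00476 over 10 libraries and p = 0.0286, the smallest the design allows, over 8 units).

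SP2509 replicates 1 and 2, and SP2509 replicates 4 and 5, differed from each other less at high read counts than any other pair of libraries of one group did. In the other 19 pairs the spread relative to the Poisson expectation rose by 4.30 to 60.6 from genes with 10 to 50 reads to genes with 1000 to 5000 reads. Between replicates 1 and 2 and between replicates 4 and 5 it rose by 0.305 and fell by 0.179. In these pairs the spread was 2.21 to 4.12 times the Poisson expectation over all bins of 10 to 10000 reads, and single transcripts differed, with Gapdh at 4129 and 1331 normalised reads in replicates 1 and 2. The mucin gene Muc5b, a product of mucous glands, stood at 270597 and 281216 normalised reads in replicates 4 and 5 and at 644 or less in every other library. SP2509 means and SDs below are therefore given over 4 units, with each of those pairs averaged. Fold changes come from the 10 libraries as designed. For called genes the adjusted p-value with the pairs merged is given as well, singly or as a range.

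**Figure D1:**
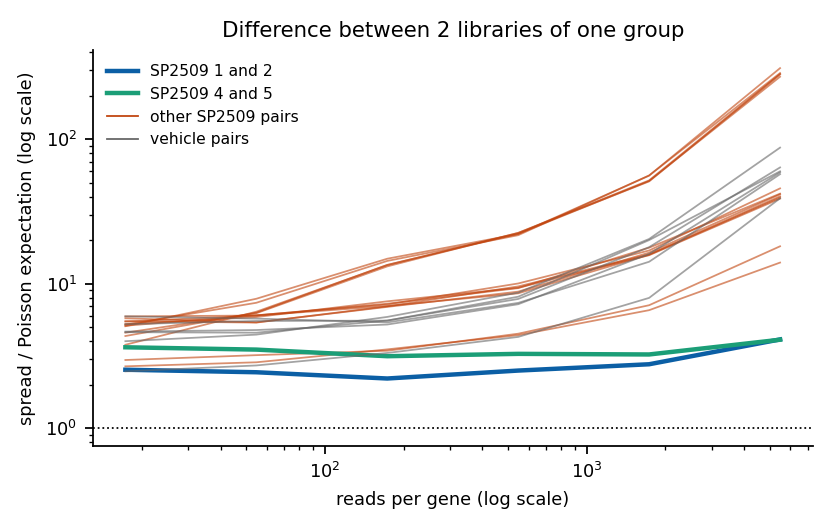
Spread between 2 libraries of one group divided by the Poisson expectation (vertical axis, log scale) against reads per gene (horizontal axis, log scale), 1 line per pair, with 1 marking the Poisson expectation. The lines of SP2509 replicates 1 and 2 and of SP2509 replicates 4 and 5 stay nearly level up to 1000 reads and rise to about 4.1 above 3000 reads, and those of the other 19 pairs climb further.

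The comparison of SP2509 with vehicle asks how LSD1 inhibition changes the tongue transcriptome, and the series title points to MHC class I, dendritic cells, CD8 T cells and the IFN-gamma, CXCL9 and CXCR3 axis. In the 10-library fit, the chaperone genes Hspa1b and Hspa8, the wound-associated keratinocyte genes Krt17 and Ereg, and the glycolytic genes Pgk1 and Ldha were higher with SP2509. The collagen genes Col5a3 and Col3a1, the neural adhesion gene Ncam1, the growth factor gene Vegfa and the dendritic cell integrin gene Itgax were lower. Of 17088 genes tested, 846 were higher and 709 lower at an adjusted p under 0.05 (limma), and quantile normalization gave 666 genes higher in SP2509 and 1060 genes lower in SP2509. With the pairs merged no gene passed (limma, lowest adjusted p = 0.0718), while 1980 higher and 1652 lower genes had an unadjusted p under 0.05, where chance gives 854 on average. All 1555 called genes were among them with the same direction. Other splits of the 8 units gave 155 to 2513 genes at that threshold. edgeR called 896 higher and 549 lower genes on the recovered reads of the 10 libraries, 1349 of them shared with limma. With the pairs summed edgeR called 0 (lowest adjusted p = 0.0707, 3855 genes at an unadjusted p under 0.05). DESeq2 with the pairs summed called 875 higher and 648 lower genes. Leaving out 1 library moved the number of genes higher in SP2509 to between 171 (without vehicle replicate 1) and 1971 (without SP2509 replicate 6).

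Kdm1a, the gene of the inhibited enzyme (chromosome 4, 136550540 to 136602723, GRCm38), had 737 ± 68.1 normalised reads in vehicle (SD, n = 4) and 748 ± 92.3 in SP2509 (n = 4 units), a log2 fold change of 0.01 ± 0.12 (SE; limma adjusted p = 0.958). Of 17 tested genes of LSD1-containing complexes 3 were lower and none higher. Zmym3 fell by 0.80 on the log2 scale (SE 0.12, adjusted p = 0.0118), from 852 ± 119 to 479 ± 39.5 normalised reads. Phf21a, a subunit that reads unmethylated histone H3, fell by 0.49 (SE 0.10, adjusted p = 0.0194). With the pairs merged the adjusted p-values of Zmym3 and Phf21a were 0.0718 and 0.0796. The list did not pass camera (adjusted p = 0.117) or fry (adjusted p = 0.065). Its mean log2 value was lower by 0.17, with every SP2509 library below every vehicle library (exact permutation p = 0.00476 over 10 libraries and 0.0286 over 8 units, and 0.0571 and 0.206 adjusted over the 36 lists).

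Of 23 genes of MHC class I antigen presentation, 21 had a positive fold change, with a median log2 fold change of 0.44. At the gene level 4 were higher over all genes tested and 8 adjusted over the list alone, where with the pairs merged 1, Canx, passed. The chaperone genes Canx (log2 fold change 0.61 ± 0.10 SE, adjusted p = 0.0118, 0.0718 merged) and Calr (0.87 ± 0.23, adjusted p = 0.0365, 0.0978 merged), which assist folding of class I and many other glycoproteins, were 2 of the 4. The non-classical class I genes H2-T22 (0.62 ± 0.16, adjusted p = 0.0326, 0.112 merged) and H2-T23 (0.49 ± 0.14, adjusted p = 0.0434, 0.158 merged) were the others. The classical heavy chain gene H2-K1 had 4511 ± 1006 normalised reads in vehicle and 6768 ± 2790 in SP2509 (log2 fold change 0.61 ± 0.29, adjusted p = 0.187). H2-D1 had 4226 ± 851 and 6533 ± 1901 (0.67 ± 0.22, adjusted p = 0.0724). The light chain gene B2m had 2533 ± 641 and 4037 ± 1218 (0.69 ± 0.23, adjusted p = 0.0777). The peptide transporter gene Tap1 (0.29 ± 0.29, adjusted p = 0.551) and the class I transactivator gene Nlrc5 (0.60 ± 0.41, adjusted p = 0.355) did not pass. The list passed camera (adjusted p = 8.8e-05) but not with an estimated correlation (adjusted p = 0.845) or in fry (adjusted p = 0.0909). Its mean log2 value differed by 0.45 (exact permutation p = 0.0524 over 10 libraries, 0.143 over 8 units). In SP2509 replicate 6 the mean log2 value of the list was 9.04, within the vehicle range of 8.96 to 9.39, against 9.49 to 9.92 in SP2509 replicates 1 to 5. Single genes varied more. In replicates 4 and 5 Tap1 (492 and 471) and Nlrc5 (268 and 263) lay within the vehicle ranges of 384 to 555 and 202 to 360. H2-K1, H2-D1 and B2m lay above every vehicle library there. Replicate 6 was below every vehicle library in H2-K1, Tap1 and Nlrc5, and within the vehicle range in H2-D1 and B2m. Reads can be shared between these closely related H2 genes, so the values of single heavy chain genes carry that uncertainty.

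**Figure D2:**
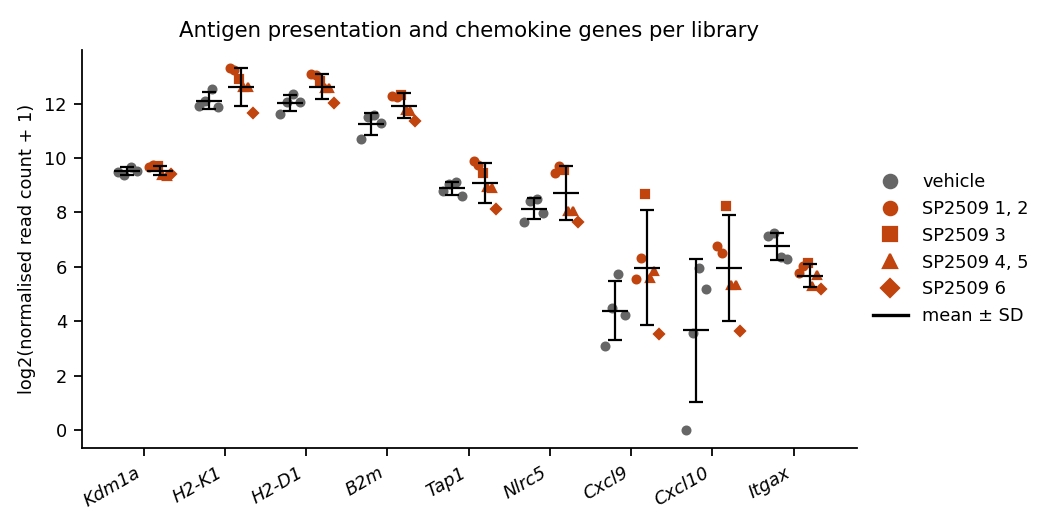
Values per library on the log2(normalised read count + 1) scale for Kdm1a and for antigen presentation, chemokine and dendritic cell genes, with vehicle in grey and SP2509 in orange, symbols marking the replicates, and bars giving mean ± SD over 4 vehicle libraries and 4 SP2509 units. SP2509 replicate 6 lies lowest of the SP2509 libraries in H2-K1, B2m, Cxcl9 and Cxcl10, and Itgax is lower in SP2509.

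Of 20 tested genes of the IFN-gamma, CXCL9 and CXCR3 axis none passed the gene test, 15 had a positive fold change and the median was 0.33. The chemokine gene Cxcl9 had 24.7 ± 19.2 normalised reads in vehicle and 133 ± 185 in SP2509 (log2 fold change 1.53 ± 0.79, adjusted p = 0.225), with 409 in SP2509 replicate 3 and 10.6 in replicate 6. Cxcl10 had 26.6 ± 27.0 and 113 ± 132 (2.31 ± 1.08, adjusted p = 0.186), with 304 in SP2509 replicate 3, 11.4 to 107 in the other SP2509 libraries and 0 in vehicle replicate 1. Without SP2509 replicate 3 the fold changes of Cxcl9 and Cxcl10 were 0.98 and 1.85, and without vehicle replicate 1 they were 1.10 and 1.08. Cxcl11, annotated as a polymorphic pseudogene, had 81.0 ± 13.6 and 77.7 ± 26.8 (-0.21 ± 0.26, adjusted p = 0.638). The members with the smallest p were the interferon-induced GTPase genes Irgm1 (0.49 ± 0.14, adjusted p = 0.0531) and Gbp2 (0.98 ± 0.31, adjusted p = 0.0665) and the kinase gene Jak1 (0.28 ± 0.09, adjusted p = 0.0662). Cd274, which encodes PD-L1, was at -0.15 ± 0.20 (adjusted p = 0.656). The list passed camera (adjusted p = 0.0375) but not with an estimated correlation (adjusted p = 0.845) or in fry (adjusted p = 0.214). Camera lost it without vehicle replicate 1, 2 or 4 or SP2509 replicate 1, 2 or 3, where its median lay between 0.26 and 0.33. The 27 genes of the type I interferon response had no gene past the threshold (median 0.19, camera adjusted p = 0.148), with Ifih1 (0.65 ± 0.25, adjusted p = 0.108) and Ifi44 (0.94 ± 0.36, adjusted p = 0.113) closest.

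T cell transcripts were scarce. Ifng, Cxcr3, Cd8a, Cd8b1 and Gzmb lay under the filter on low values and were not tested. Cd8a rested on 16 reads in all vehicle libraries together and 39 in all SP2509 libraries (5.92 ± 5.42 and 5.06 ± 2.32 normalised reads). Cd8b1 rested on 7 and 16 reads, Ifng on 2 and 16, Gzmb on 1 and 18 and Cxcr3 on 22 and 20. Gzmb was at 0 to 0.898 normalised reads in the vehicle libraries and at 1.45 to 4.15 in the SP2509 libraries. Of 9 tested members of the CD8 and cytotoxic T cell list, Trbc2, a T cell receptor beta constant gene, was higher (1.32 ± 0.26, adjusted p = 0.0151, 0.0749 merged) at 82.1 ± 20.4 against 32.6 ± 9.71 normalised reads. Its near-identical neighbour Trbc1, with which it can share reads, was at -0.22 ± 0.34 (adjusted p = 0.716). Lck, a T cell kinase gene, was at -1.15 ± 0.35 (adjusted p = 0.0583). As a list they did not pass (median -0.09 but mean 0.04, camera adjusted p = 0.975). The 11 tested genes of checkpoints and regulatory T cells had none past the threshold (median 0.10 and camera direction down, adjusted p = 0.975).

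Among 21 dendritic cell genes, 1 was lower and 15 had a negative fold change. Itgax, which encodes CD11c, fell by 1.06 on the log2 scale (SE 0.27, adjusted p = 0.0351, 0.108 merged), from 112 ± 38.3 to 52.3 ± 15.4 normalised reads. It stood at 139 and 150 in vehicle replicates 1 and 2, at 81.6 and 76.3 in vehicle replicates 3 and 4, and at 35.0 to 69.8 in SP2509. Flt3, the receptor that sustains dendritic cell development, was at -1.497 ± 0.45 (adjusted p = 0.0581), and Wdfy4 at -0.72 ± 0.27 (adjusted p = 0.105). The cross-presenting subset genes Xcr1 (-0.10 ± 0.88, adjusted p = 0.96) and Clec9a (-0.23 ± 0.30, adjusted p = 0.655) did not differ by more than the replicate spread. The list passed fry (adjusted p = 0.018) and not camera (median -0.37, adjusted p = 0.067, 0.605 with an estimated correlation). Its mean log2 value was lower by 0.36 (exact permutation p = 0.00952 over 10 libraries, 0.0286 over 8 units). Of 7 tested B cell and plasma cell genes 2 had a positive fold change, and adjusted over the list alone 2 were lower and 1 higher. Over all genes tested the heavy chain gene Ighm fell by 0.94 (SE 0.25, adjusted p = 0.0378, 0.102 merged). Igkc was at -1.91 ± 0.59 (adjusted p = 0.0597). That list too passed fry (adjusted p = 0.018) and not camera (adjusted p = 0.417, 0.845 with an estimated correlation). Its mean log2 value was lower by 0.38 (exact permutation p = 0.00476 over 10 libraries, 0.0286 over 8 units). Of 12 MHC class II genes H2-Ob fell by 1.33 (SE 0.38, adjusted p = 0.0476, 0.0891 merged). Camera did not call this list (camera adjusted p = 0.914).

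Of 17 macrophage and monocyte genes 2 were higher and 1 lower. Arg1, an arginine-degrading enzyme gene of alternatively activated macrophages and of liver, rose by 3.03 (SE 0.69, adjusted p = 0.0238, 0.0726 merged). The complement gene C1qb rose by 0.92 (SE 0.24, adjusted p = 0.0357, 0.124 merged). The phagocytic receptor gene Mertk fell by 0.53 (SE 0.13, adjusted p = 0.0333, 0.108 merged). The list itself did not pass (camera adjusted p = 0.198). The 8 neutrophil genes had none past the threshold (camera adjusted p = 0.285), with S100a8 at 1.92 ± 0.56 (adjusted p = 0.0514) and S100a9 at 2.22 ± 0.75 (adjusted p = 0.0818). Neither had the 7 mast cell genes (camera adjusted p = 0.975).

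Genes of protein folding formed the list with the smallest camera p. Of 18 heat shock and unfolded protein response genes 8 were higher, 16 had a positive fold change and the median was 0.79 (camera adjusted p = 2.8e-06, 0.702 with an estimated correlation, fry adjusted p = 0.018). Hspa1b rose by 1.11 (SE 0.21, adjusted p = 0.0147, 0.0784 merged). Its near-identical copy Hspa1a rose by 0.90 (SE 0.20, adjusted p = 0.0222, 0.0751 merged). The constitutive chaperone gene Hspa8 rose from 10963 ± 1433 to 19680 ± 3169 normalised reads (log2 fold change 0.80 ± 0.18, adjusted p = 0.0229, 0.0796 merged). The ER stress gene Herpud1 rose from 686 ± 113 to 1580 ± 627 (1.15 ± 0.26, adjusted p = 0.024, 0.0751 merged), with 2393 and 2271 in SP2509 replicates 4 and 5, the libraries with high Muc5b, and 1010 to 1861 in the other SP2509 libraries. The mean log2 value of this list was higher by 0.75, with every SP2509 library above every vehicle library (exact permutation p = 0.00952 over 10 libraries, 0.0286 over 8 units). It was 10.3 and 10.2 in replicates 4 and 5 and 9.48 to 9.80 in the other SP2509 libraries, and without replicates 4 and 5 the median of the heat shock and unfolded protein response list was 0.66.

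The 13 stress keratin and wound response genes held 3 higher genes, with a median of 1.14. Krt17, a keratin of activated keratinocytes, rose from 11729 ± 3957 to 28455 ± 12956 normalised reads (1.24 ± 0.31, adjusted p = 0.0319, 0.121 merged). Ereg, an EGF receptor ligand gene, rose by 2.28 (SE 0.40, adjusted p = 0.0125, 0.0718 merged) and Lcn2, which encodes an iron-scavenging antimicrobial protein, rose by 2.85 (SE 0.73, adjusted p = 0.0347, 0.122 merged). The list passed camera (adjusted p = 0.0113) but not with an estimated correlation (adjusted p = 0.845) or in fry (adjusted p = 0.228). Its mean log2 value in SP2509 replicate 6, 7.33, was below the vehicle mean of 7.43. Of 25 differentiated keratinocyte genes Klf4 rose by 0.49 (SE 0.12, adjusted p = 0.0316, 0.13 merged) and the list did not pass (camera adjusted p = 0.067). Neither did 15 basal keratinocyte genes (camera adjusted p = 0.285) or 8 filiform papilla and hair-type keratin genes (camera adjusted p = 0.844), none of which passed singly. Of 25 proliferation genes the replication licensing gene Mcm2 rose by 0.998 (SE 0.20, adjusted p = 0.0157, 0.0801 merged). Taken as a list, these genes did not pass (camera adjusted p = 0.285).

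Of 19 hypoxia and glycolysis genes 4 were higher and 1 lower. Pgk1 rose from 826 ± 278 to 2264 ± 911 normalised reads (1.37 ± 0.26, adjusted p = 0.0136, 0.0718 merged). Ldha rose by 1.07 (SE 0.21, adjusted p = 0.0149, 0.0751 merged). Eno1 rose by 0.81 (SE 0.17, adjusted p = 0.0183, 0.0839 merged). Vegfa, the endothelial growth factor gene, moved the other way, from 12189 ± 1646 to 5800 ± 2602 normalised reads (-1.30 ± 0.25, adjusted p = 0.0137, 0.0792 merged). This list did not pass (camera adjusted p = 0.148). Of 22 nuclear genes of oxidative phosphorylation 21 had a positive fold change and 1, Cox5a, passed (1.22 ± 0.32, adjusted p = 0.0377, 0.1 merged). The list passed camera (median 0.55, adjusted p = 0.000172, 0.845 with an estimated correlation, fry adjusted p = 0.328). Its mean log2 value was 12.8 in SP2509 replicate 6, 11.6 to 11.7 in the other SP2509 libraries and 10.7 to 11.6 in vehicle. For the list Oxidative phosphorylation (nuclear) the median was 0.36 without SP2509 replicate 6 (camera adjusted p = 0.00204) and 0.35 without vehicle replicate 1 (camera adjusted p = 0.0107). All 13 mitochondrially encoded genes had a negative fold change and 6 were lower (median -1.06, camera adjusted p = 0.000172, 0.845 with an estimated correlation, fry adjusted p = 0.018), in step with the lower mitochondrial share of reads. mt-Nd2 fell by 1.08 (SE 0.28, adjusted p = 0.0359, 0.148 merged) and mt-Co3 fell by 1.14 (SE 0.30, adjusted p = 0.0359, 0.116 merged). Skeletal muscle genes, 20 of 25 with a positive fold change and none past the threshold, passed camera as a list (median 0.52, adjusted p = 0.0278, 0.845 with an estimated correlation, fry adjusted p = 0.483). Their mean log2 value too was highest in SP2509 replicate 6, at 14.2 against 13.1 or less in the other SP2509 libraries. Camera lost the skeletal muscle list without SP2509 replicate 6 (median 0.33, adjusted p = 0.361), vehicle replicate 1 (0.32, adjusted p = 0.161) or vehicle replicate 4 (0.52, adjusted p = 0.0829).

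**Figure D3:**
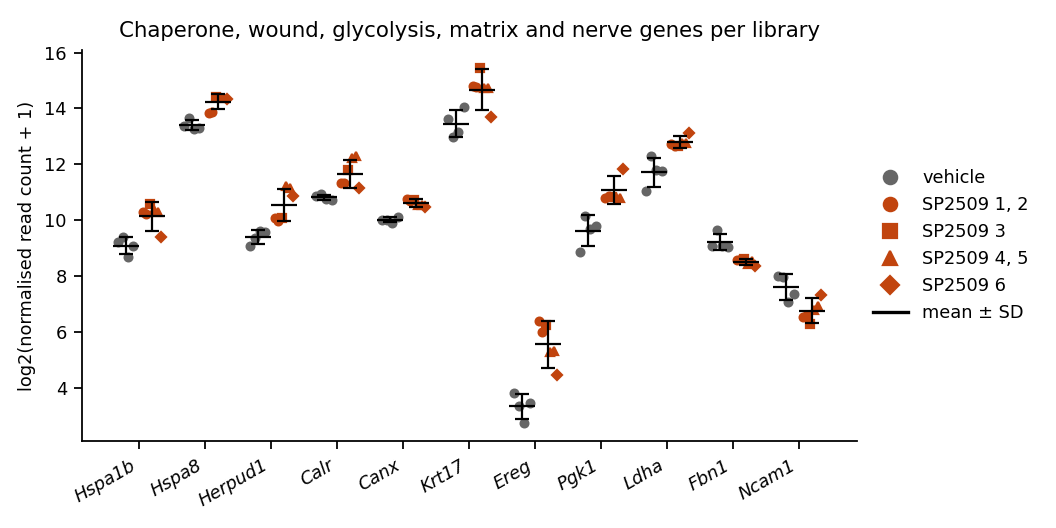
Values per library on the log2(normalised read count + 1) scale for members of the protein folding, MHC class I, wound response, glycolysis, matrix and nerve lists, with symbols and bars for vehicle (4 libraries) and SP2509 (6 libraries, 4 units) as in the plot of antigen presentation genes. Ereg, Pgk1, Ldha and Canx lie higher and Fbn1 lower in every SP2509 library than in any vehicle library.

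Of 19 fibroblast and extracellular matrix genes 4 were lower and none higher. Fbn1, which encodes a microfibril protein, fell by 0.69 (SE 0.13, adjusted p = 0.0135, 0.0734 merged). Col5a1 fell by 0.73 (SE 0.17, adjusted p = 0.0261, 0.104 merged). Col3a1 fell by 0.67 (SE 0.19, adjusted p = 0.0427, 0.123 merged) and Col6a1 fell by 0.45 (SE 0.12, adjusted p = 0.0442, 0.126 merged). Adjusted over the list alone 8 were lower and 2, Fbln1 and Lum, higher, and with the pairs merged the 4 named first passed. Over all genes tested Fbln1 was at 0.80 ± 0.24 (limma adjusted p = 0.0581) and Lum at 0.64 ± 0.21 (limma adjusted p = 0.0691). The whole list did not pass (median -0.03, camera adjusted p = 0.153). Of 14 nerve and Schwann cell genes 13 had a negative fold change and 2 were lower. Ncam1 fell by 0.85 (SE 0.24, adjusted p = 0.0449, 0.14 merged). The list passed camera (median -0.67, adjusted p = 8.8e-05, 0.605 with an estimated correlation, fry adjusted p = 0.018). The mean log2 value of the nerve list was lower by 0.59 (exact permutation p = 0.0143 over 10 libraries, 0.0571 over 8 units).

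None of the lists that follow passed camera, though some held called genes. The matrix gene Tnc rose by 1.496 (SE 0.39, adjusted p = 0.0366, 0.138 merged). The transcription factor gene Zeb1 fell by 0.58 (SE 0.15, adjusted p = 0.0359, 0.122 merged) among 21 genes of epithelial to mesenchymal transition (camera adjusted p = 0.826). Ccn2 rose by 1.02 (SE 0.28, adjusted p = 0.0415, 0.113 merged) and Skil by 0.44 (SE 0.12, adjusted p = 0.0444, 0.121 merged) among 15 YAP and TGF-beta targets (camera adjusted p = 0.18). Fos rose by 1.28 (SE 0.31, adjusted p = 0.0287, 0.107 merged) and Ier3 by 0.78 (SE 0.18, adjusted p = 0.0247, 0.0751 merged) among 17 immediate early genes (camera adjusted p = 0.18). Phlda3, a p53 target, rose by 0.90 (SE 0.19, adjusted p = 0.0181, 0.0734 merged) among 17 genes of the p53 response (camera adjusted p = 0.975). The pericyte gene Mcam fell by 0.47 (SE 0.11, adjusted p = 0.0254, 0.11 merged) among 12 smooth muscle and pericyte genes (camera adjusted p = 0.975). Car3 (2.76 ± 0.79, adjusted p with the pairs merged 0.143) was the 1 higher gene among 12 adipocyte genes (camera adjusted p = 0.128). No member passed among 18 NRF2 response genes (camera adjusted p = 0.213), 15 endothelial genes (camera adjusted p = 0.975), 10 myogenic genes (camera adjusted p = 0.417), 7 taste cell genes (camera adjusted p = 0.776), 6 erythrocyte genes (camera adjusted p = 0.224) or 4 gland genes (camera adjusted p = 0.231). In the p53, smooth muscle and endothelial lists the medians were positive (0.056, 0.25 and 0.14) while camera's direction was down. In the mast cell list the median was 0.12 and the mean -0.049, and in the taste cell list the median was -0.11 and the mean 0.20.

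Among called genes with an official symbol and a mean of at least 50 normalised reads in the higher group, the largest increase was that of Wfdc18 (chromosome 11, 83709015 to 83711348), a whey acidic protein family gene, at 19.2 ± 13.7 normalised reads in vehicle and 1988 ± 3345 in SP2509 (log2 fold change 5.03 ± 1.42, adjusted p = 0.0492, 0.0832 merged), with 7053 in the highest SP2509 library and 58.1 in the lowest. Nppb (chromosome 4, 147985788 to 147987205), which encodes brain natriuretic peptide, rose from 3.97 ± 5.51 to 55.8 ± 41.8 (4.00 ± 0.75, adjusted p = 0.0136, 0.0751 merged). After Arg1 and Lcn2 came Car3, a carbonic anhydrase gene of muscle and fat (2.76 ± 0.79), the keratin genes Krt42 (2.64 ± 0.57) and Krt7 (2.20 ± 0.54), Ereg, Osr2 (2.10 ± 0.53) and the cilia gene Cfap298 (2.07 ± 0.39). Adjusted p-values of these genes ran from 0.0125 for Ereg to 0.0492 for Wfdc18, and with the pairs merged from 0.0718 for Ereg to 0.143 for Car3. Wfdc18 (6918 and 7053 normalised reads), Car3 (1511 and 1401), Arg1 (372 and 298), Lcn2 (376 and 366), Krt7 (252 and 220), Osr2 (269 and 275) and, by less, Cfap298 (115.3 and 101.1, with 98.3 in replicate 1) were highest in SP2509 replicates 4 and 5. In the same libraries Muc5b (log2 fold change 5.06 ± 3.69, adjusted p = 0.402) and the adipocyte gene Cfd (1180 and 1161, and 122 or less elsewhere) were highest too. Without them the fold changes were 3.17 for Wfdc18 (adjusted p = 0.0668), 1.68 for Car3 (adjusted p = 0.0833), 2.39 for Lcn2 (adjusted p = 0.118), 1.84 for Krt7 (adjusted p = 0.107) and 1.97 for Cfap298 (adjusted p = 0.0568), which did not pass, and 2.12 for Arg1 (adjusted p = 0.0498) and 1.35 for Osr2 (adjusted p = 0.0483). Within the same limits the largest decreases were those of Grin2c (chromosome 11, 115249169 to 115267243), an NMDA receptor subunit gene, from 278 ± 110 to 70.8 ± 31.3 (-2.14 ± 0.42, adjusted p = 0.0149, 0.0718 merged), and of Fgd3 (chromosome 13, 49261554 to 49320311), a Cdc42 exchange factor gene, from 420 ± 116 to 107 ± 37.0 (-2.10 ± 0.27, adjusted p = 0.0118, 0.0718 merged). Col5a3 (chromosome 9, 20770050 to 20815067) stood at 2715 and 2713 in vehicle replicates 1 and 2 and at 987 and 1293 in vehicle replicates 3 and 4. In SP2509 it stood at 343 to 613. Its mean went from 1927 ± 917 to 501 ± 99.3 (-1.84 ± 0.28, adjusted p = 0.0118, 0.0718 merged). They were followed by the pseudogene Akp-ps1 (-1.83 ± 0.36), the lipase gene Pnpla3 (-1.70 ± 0.44), Sntg2 (-1.58 ± 0.34), Mroh7 (-1.53 ± 0.25), the nicotinic receptor gene Chrna10 (-1.49 ± 0.39), Rimklb (-1.48 ± 0.24) and Cfap100 (-1.47 ± 0.34), with adjusted p-values from 0.0118 for Mroh7 and Rimklb to 0.0361 for Chrna10, and with the pairs merged from 0.0718 for Mroh7 and Rimklb to 0.107 for Chrna10. Among these genes the spans of Ereg, Krt7, Cfap298, Grin2c, Col5a3, Pnpla3, Chrna10, Rimklb and Cfap100 overlap another annotated gene. Of the genes tied to the series title, so do those of Kdm1a, Cxcl10, Cxcl11, Ifng, B2m, Tap1, Nlrc5, Clec9a and Cd274. Whole spans were compared and not exons, and the strand setting is not known, so whether reads are shared is open.

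Over all 36 lists tested, camera called 8, and the same 8 with the pairs merged, while 0 passed camera with an estimated correlation and fry called 5. Of 100 splits of the 10 libraries into 6 and 4, the real one included, 74 gave 8 or more called lists, and 1 gave as many called genes. For called genes this share overstates the distance from chance, since every split with a call kept both close pairs whole.

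**Figure D4:**
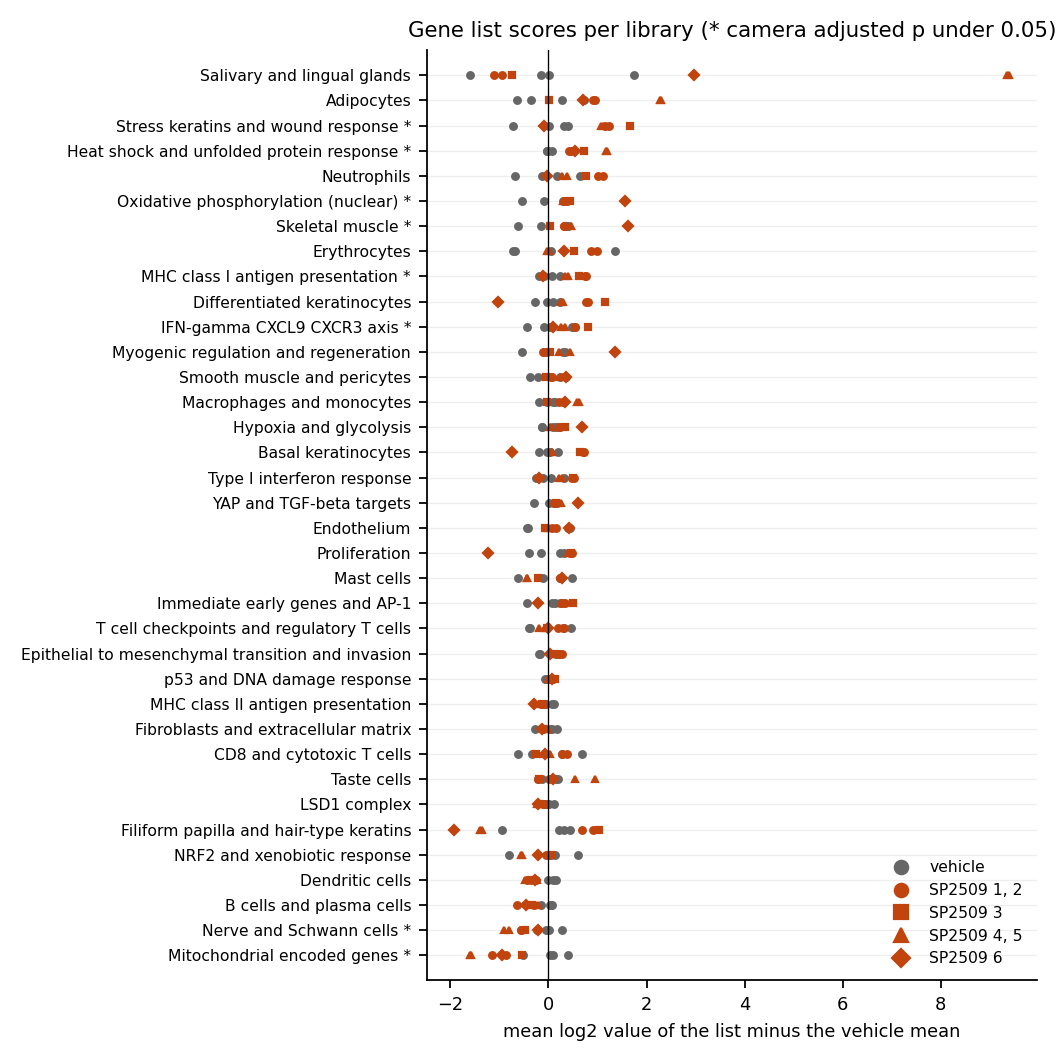
Mean log2 value of each gene list per library minus the mean of the 4 vehicle libraries (horizontal axis) for 36 lists ordered by median fold change, with vehicle in grey, SP2509 in orange and symbols marking the replicates. Only the heat shock list, among lists called as higher, has every SP2509 library above every vehicle library, and SP2509 replicates 4 and 5 stand far to the right in the gland list.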

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

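The tests of replicate closeness, of thinning and of the MHC class I list were chosen after the results they bear on were seen. Of 100 groups of values examined (50 measures in 2 groups), 5 had a library far from the rest of its group, and chance gives about 5. In SP2509 replicate 6 the mean log2 value of the stress keratin list was the lowest at 7.33 against 8.51 in the next library (gap over range 0.666). In the same library the nuclear oxidative phosphorylation list was the highest, at 12.8 against 11.7 (0.888), and so was the skeletal muscle list, at 14.2 against 13.1 (0.725). Ifng stood apart in vehicle replicate 1 and Gzmb in vehicle replicate 4, each with reads in 1 library and 0 in the other vehicle libraries (gap over range 1 for both).

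SP2509 replicates 1 and 2, and replicates 4 and 5, differ less at high read counts than any other pair of one group. The values of the 2 libraries of a pair differ, so they do not hold the same reads. The lowest spread in these pairs over all bins was 2.21 times the Poisson expectation. If repeat sequencing adds Poisson noise only, this argues against 1 library sequenced under both names. Single transcripts differed too, with Gapdh at 4129 and 1331 normalised reads in replicates 1 and 2. In replicates 4 and 5 mt-Co2 stood at 11368 and 35413. At 10 to 30 reads the spread was 2.54 for SP2509 replicates 1 and 2, but also 2.47 for vehicle replicates 3 and 4. The noise floor of these data may thus lie above Poisson, so 1 library under both names is not excluded. Libraries made from one tissue were taken to differ by technical noise that, relative to Poisson, does not grow with read count. That premise was assumed and not measured. From 10 to 50 reads to 1000 to 5000 reads the largest growth in these pairs was 0.305, against at least 4.30 in the other 19 pairs. Up to 3000 to 10000 reads it was 1.58 for replicates 1 and 2 and 0.465 for replicates 4 and 5, against at least 11.3 elsewhere, so 2 libraries of one tissue may be the source of each pair but this stays open. No biological explanation was tested, and mice of very similar tissue composition remain open.

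The 1555 genes called between SP2509 and vehicle were not matched by other groupings: 1 of 100 splits of the 10 libraries, the real one, gave as many, and the highest other split gave 3. Other splits often part the 2 libraries of a close pair, which favours few calls. Every split with a call kept both pairs whole, so 1 of 100 overstates the distance from chance. With the pairs merged 1 of 35 splits of the 8 units gave 3632 or more genes at an unadjusted p under 0.05, the highest other split giving 2513, while 8 called lists or more came from 74 of 100 splits, up to 21, so chance cannot be excluded for the number of lists and the libraries share broad structure beyond treatment. Fewer reads in vehicle are argued against as the whole cause by 1393 calls after thinning. A collection time peculiar to vehicle replicates 1 and 2, whose clock genes stand apart, stays open. Without these libraries the fold changes of the 1555 genes kept a median ratio of 0.922 to the full fit (quartiles 0.801 and 1.05). Leaving out any other pair of vehicle libraries gave medians of 0.894 to 1.11. The genes were called for a difference from all vehicle libraries, which favours a ratio near 1, so the ratio cannot decide. The treatment, an untested difference between groups in handling that may also have set the mitochondrial share, and a time of collection that differed between all vehicle and all SP2509 mice remain open as well.

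The MHC class I list was higher in SP2509 in camera (adjusted p = 8.8e-05), but did not pass with an estimated correlation (adjusted p = 0.845) or in fry (adjusted p = 0.0909). How much of this is due to the chaperone genes Calr, Canx and Pdia3, which also answer ER stress, stays open. The other 20 members had a median of 0.40 and passed camera (adjusted p = 0.00111), but not with an estimated correlation (adjusted p = 0.845) or in the exact permutation of their score (p = 0.0857 over libraries, 0.2 over units). With the differentiated keratinocyte score as a covariate the median was 0.30 against 0.44, which leaves open how much a larger share of keratinocytes may add, because that score itself lies lowest in SP2509 replicate 6. Induction by SP2509, as the series title has it, stays open as well, with an exact permutation p of 0.0524 over libraries and 0.143 over units.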

How the results depend on the processing

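The merged pairs, the random block, the sets of libraries left out together, the length and GC correction, thinning, the keratinocyte covariate and the permutation of list scores were added after seeing the data. The cause of a change was not tested unless the setting shows it. All 21 called named genes kept their direction in each of their 648 alternative values.

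The counts of genes higher in SP2509 (846) and genes lower in SP2509 (709) became 553 higher without the filter, 490 higher without trend and robust, 2381 and 1778 with library weights, and 1334 higher with the muscle score. They became 1668 and 1274 in DESeq2, 1644 and 1144 with the keratinocyte score, 1713 and 1388 at an adjusted p of 0.10, and 97 and 179 with a minimum log2 fold change of 1. They fell to 220 and 135 with the unit as a random block (correlation 0.841) and to 219 and 156 without SP2509 replicates 4 and 5. Both were 0 with pairs merged (3632 genes at an unadjusted p under 0.05; at an adjusted p under 0.10, 488 and 366), with pairs summed in edgeR (3855) and without vehicle replicates 1 and 2 (3431). The median standard error of called genes rose from 0.146 to 0.169 on merging while their median size went from 0.65 to 0.64. Quantile normalization gave 666 and 1060 and so turned the split. Leaving out 1 library gave 171 to 1971 higher and 107 to 1488 lower genes. Higher genes numbered 171, 378 and 483 without vehicle replicates 1, 3 and 4, and 382, 455, 391, 464, 428 and 1971 without SP2509 replicates 1 to 6, and lower genes 402 without vehicle replicate 2.

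The replicate block gave 1158 and 813 genes and 14 lists. Numbers 1 to 4 correlated at 0.126, 0.032, -0.198 and 0.125, and libraries correlated best with their own number only for number 4. Lists called (8) were 18 without the filter, 5 with the strict filter, 5 in fry and 0 with an estimated correlation.

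MHC class I lost its call, at a median of 0.44, with an estimated correlation and in fry, and in the exact permutation of its score (0.45, merged 0.40). The IFN-gamma list lost its call at 0.33 (strict filter, estimated correlation, fry, length and GC correction), 0.26 (quantile, muscle score), 0.32 (edgeR), 0.28 (keratinocyte score) and 0.17 (without vehicle replicates 1 and 2), also in the permutation (0.43, merged 0.44) and without vehicle replicates 1, 2 and 4 and SP2509 replicates 1, 2 and 3 singly, the leave-one-out medians running from 0.26 to 0.41. Dendritic cells gained a call at -0.38 (no filter), -0.37 (no trend; fry), -0.43 (replicate block), -0.27 (without SP2509 replicates 4 and 5) and without vehicle replicate 1 or 3 or SP2509 replicate 5, with leave-one-out medians from -0.38 to -0.22.

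Reversed values belong to results near 0. The CD8 and cytotoxic T cells list went to 0.30 (no filter), 0.028 (quantile), 0.23 (without SP2509 replicates 4 and 5) and 0.042 (permutation), changed direction in fry at -0.093, and ran from -0.32 to 0.19 in leave-one-out fits. Xcr1 went to 0.59 (pseudocount 0.1) and ran from -1.15 to 0.52 (leave-one-out). Kdm1a went to -0.046 (quantile), -0.079 (without vehicle replicates 1 and 2), -0.03 (thinned) and -0.044 (keratinocyte score) and ran from -0.039 to 0.068 (leave-one-out). Cd274 went to 0.054 (weights) and 0.098 (without vehicle replicates 1 and 2) and ran from -0.28 to 0.0022 (leave-one-out). Several T cell genes rest on under 40 reads per group and were not tested.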

Other observations

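The gene families and clock genes below were chosen after the data were seen, and the tests of clock genes across the called genes were fixed before their results. The counts of families are given without a test, since one on genes chosen by their values would decide nothing. Of 37 tested proteasome subunit genes 15 were called, all higher with SP2509, and 22 did not pass. The median log2 fold change of the 37 was 0.41, and 0.32 after quantile normalization. Psmb7 was at 1.51 ± 0.22 (SE, adjusted p = 0.0118, 0.0718 merged) and Psma6 at 0.75 ± 0.13 (adjusted p = 0.0125, 0.0718 merged). Of 8 subunit genes of the CCT chaperonin, which folds actin and tubulin, 6 were called, all higher, with a median of 0.55 over the 8. Tcp1 was at 0.72 ± 0.10 (adjusted p = 0.0118, 0.0718 merged).

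Of 39 collagen chain genes tested 12 were called, all lower, and 27 did not pass. Some of the 27 lay the other way, the furthest being Col8a1 (0.68 ± 0.23, limma adjusted p = 0.0741) and Col12a1 (0.65 ± 0.25, limma adjusted p = 0.111). Col1a1 (-0.37 ± 0.15, limma adjusted p = 0.136) and Col1a2 (-0.03 ± 0.12, limma adjusted p = 0.906) did not pass either. The median over the 39 was -0.43, and -0.49 after quantile normalization. Beside Col5a3 the called genes included Col24a1 (-0.85 ± 0.14, adjusted p = 0.0118, 0.0718 merged) and the basement membrane gene Col4a2 (-0.58 ± 0.11, adjusted p = 0.0149, 0.0796 merged). With the pairs merged no gene of these families passed in limma, and 24 proteasome and 7 CCT genes were higher and 17 collagen genes lower at an unadjusted p under 0.05. Of the higher calls 96.7% were protein-coding genes, against 85.2% of the lower calls and 85.3% of all tested genes.

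Clock genes set vehicle replicates 1 and 2 apart from vehicle replicates 3 and 4. Arntl, an activator of the clock, had 367 and 335 normalised reads in vehicle replicates 1 and 2, 118 and 96.1 in replicates 3 and 4, and 65.1 to 112 in SP2509. Dbp, an output gene in opposite phase, had 229.9 and 230.3, then 2520 and 1901, and 334 to 1184 in SP2509. Per2 had 252 and 303, then 1098 and 822, and 1259 to 1709 in SP2509 (1.504 ± 0.35 over all libraries, adjusted p = 0.0247, 0.0944 merged). Cry1 was higher with SP2509 (0.89 ± 0.23, adjusted p = 0.0361, 0.105 merged) and Nr1d1 lower (-1.22 ± 0.32, adjusted p = 0.0362, 0.0864 merged), and without vehicle replicates 1 and 2 none of the 3 passed in limma, with Per2 at 0.61 (adjusted p = 0.108), Cry1 at 1.27 (adjusted p = 0.0899) and Nr1d1 at -1.59 (adjusted p = 0.109).

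A candidate explanation is that the tissues were collected at different times of day. Clock genes differed in their order: vehicle replicates 3 and 4 lay nearer to SP2509 in Arntl and Per2, and replicates 1 and 2 did in Cry1 and Nr1d1. Genes of different phase need not share 1 order of libraries, so this does not speak against time of day. Cry1 had 172 and 152 normalised reads in vehicle replicates 1 and 2, 120 and 75.4 in replicates 3 and 4, and 174 to 282 in SP2509. If the order of Arntl and Per2 ran through the treatment difference, vehicle replicates 3 and 4 would lie nearer to SP2509 than replicates 1 and 2 in most called genes. They did in 66.6% of them, between the bounds fixed for and against. The other ways of pairing the vehicle libraries gave 74.0% and 61.6%. Genes that follow time of day can differ in phase, so these percentages cannot decide for or against it. The share attributable to time of day stays open. Leaving out any pair of vehicle libraries gave between 0 and 697 called genes, so the 0 calls without replicates 1 and 2 (3431 at an unadjusted p under 0.05 in limma) are not peculiar to that pair.

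H19, an imprinted transcript abundant in growing muscle, stood at 13293 normalised reads in SP2509 replicate 6 and at 3489 or less elsewhere. Gapdh ranged from 598 to 9325 normalised reads over the 10 libraries.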
